A study of Oncorhynchus mykiss with 30 samples.

How the data were processed

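Methylated DNA immunoprecipitation sequencing (MeDIP-seq) was made from red blood cells (RBC) and sperm of adult male steelhead trout sampled at a hatchery and on the Methow River in Washington State, per the labels. Per the labels' protocols, DNA was broken to 200 to 800 bp with a probe sonicator or a Covaris instrument, methylated fragments were captured with an antibody against 5-methylcytosine, and sperm DNA came from single fish or from pools of 3 to 5 fish. The labels do not say which libraries were pooled or which instrument broke the DNA of each. The labels describe the libraries of a group as separate samples without saying that each came from its own fish, so p-values measure the spread between these samples, which may in part be technical.

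The deposited files were 8 tables, one for each pairwise comparison the authors made, and all held the same 2310947 windows of 1000 bp. The read counts per window and library were made by the authors and deposited as whole numbers without normalisation. Each deposited table also held the authors' own p-value and adjusted p-value per window, which were given exactly where the counts of the 6 libraries summed to 50 or more. The submitters' processing notes name FastQC, Trimmomatic, Bowtie2, SAMtools and edgeR without versions. The genome build, the alignment settings and the treatment of duplicate reads are not given in the sources used here. The highest count in any window lay between 1746 and 2072 in every library, although the libraries' totals ranged from 50.9 to 136 M reads.

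The windows lay on 29 chromosomes, numbered here in the order of their sequence identifiers, on the mitochondrial genome (17 windows) and on one joined sequence of unplaced scaffolds (360952 windows, 15.6%). Positions on the unplaced sequence are positions in that joined sequence, not places on a chromosome. All positions are those of the authors' tables. The gene table at hand belonged to another assembly (USDA_OmykA_1.1), and coordinates were not carried over, so regions are named by position only. The 10 promoter comparisons and the 11 gene lists fixed before the data were examined could not be run for the same reason. Of the 184 columns in the tables, 46 were used: 30 columns of counts, so that each library entered once, and the authors' p-values and adjusted p-values. The 66 other columns of values per library were not used.

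The 30 libraries formed 10 groups of 3. Set 1 held natural-origin fish and hatchery fish whose growth was labelled Standard. Set 2 held natural-origin fish, fast-growth hatchery fish that reached the smolt stage within 1 year and slow-growth hatchery fish that took 2 years. Each group had 3 RBC and 3 sperm libraries. Differences were coded as hatchery minus natural, slow minus fast and sperm minus RBC. Comparisons were fixed within a set, as in the deposited tables, and the sets also separated on the first principal component.

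Each comparison was tested with edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3) on the counts as deposited, with TMM scaling factors. The 8 pairwise fits used the 6 libraries of both groups and had 4 residual degrees of freedom. Windows entered when their counts over the 6 libraries summed to at least 30. The tissue comparisons and the interactions of tissue with origin or growth were fitted over all libraries of a set, with a mean count of at least 5. P-values were adjusted by the Benjamini-Hochberg method over the tested windows, and a window was called at an adjusted p under 0.05. The trend of the dispersion on abundance was estimated from 100000 windows drawn at random with a fixed seed. This form of the fit (edgeR's default, and a trend from a sample) was chosen after the counts of calls under an exact test, a fit with bias-adjusted deviances and a trend over every window had been seen for 2 of the comparisons, and those forms are given as alternatives. Levels are given as normalised CPM of the scaled library, with the SD over 3 libraries, and differences as log2 values with standard errors or as folds computed from them.

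Windows were named by a rule fixed before the data were examined. Windows at an unadjusted p under 1e-05 were merged into regions across gaps of at most 1 window, regions were ranked by their smallest p, and the first 10 per direction were kept in which every library of one group lay above every library of the other. Chance alone gives such complete separation in 10% of orders of 3 against 3. An exact permutation test of 3 against 3 cannot go below p = 0.1 (two-sided), so single windows rest on the model across all windows. The first 5 named windows per direction of each comparison between fish and of sperm against RBC in each set were followed through the alternatives run for that comparison.

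Several choices were changed one at a time. Those fixed before the data were examined were edgeR's RLE factors or library totals in place of TMM, no filter or a higher minimum count (90 summed, or a mean of 15), DESeq2's Wald test (DESeq2 1.42.0), edgeR's exact test, all 9 libraries of a tissue of set 2 in one fit, the title number as a block, and leaving out each replicate in turn (48 pairwise fits, and 12 fits of the tissue and interaction models). The leave-out fits kept the scaling factors of the full data and a dispersion trend from 50000 windows. Alternatives chosen after seeing the data took out each library's loess trend of log count on window abundance (span 0.3), corrected the counts for a ceiling of 2100 reads per window, estimated the trend over every tested window, or used bias-adjusted deviances. An alternative planned for windows with a CpG coupling value was not run, since no such value was used here.

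The test was checked on simulated counts drawn for 300000 of the real windows of each comparison with the real means and library sizes, in which 100 windows were changed by 2-fold and 100 by 4-fold. The pairwise fits recovered 14% (sperm of fast and slow fish) to 39% (RBC of set 1) of the 2-fold windows and 70% (sperm of fast and slow fish) to 81% (RBC of fast and slow fish) of the 4-fold windows. False calls ranged from 2 among 95 calls (sperm of natural and fast fish) to 9 among 111 (RBC of natural and fast fish). The simulated libraries held no trend on window abundance, so the check cannot show false calls that come from such a trend. The tissue fits recovered 60% and 74% of the 2-fold windows and 95% and 99% of the 4-fold windows in set 1 and set 2. This check was written after the fit had first been run on the deposited counts. Intervals of shares are exact Clopper-Pearson intervals at 95% and cover counting error only, taking windows as independent although neighbouring windows vary together and all come from the same libraries.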

Results

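The study captured methylated DNA from red blood cells (RBC), which keep their nucleus in fish, and from sperm of adult male steelhead, the sea-going form of rainbow trout. It asked where DNA methylation differed between natural-origin fish and fish raised in a hatchery, and between hatchery fish grown fast or slowly before release. A window with more reads held more captured DNA relative to the rest of its library, which is not a percentage of methylated cytosines. No library of uncaptured DNA was among the 30 samples. A difference in methylation thus cannot be told apart from a difference in the amount of DNA at a window. The 30 libraries formed 10 groups of 3. In set 1, the group means were 90.7 M reads for natural RBC, 125 M for hatchery RBC, and 109 M each for natural and hatchery sperm. In set 2 they were 68.5 M for natural RBC, 90.4 M for fast RBC, 65.0 M for slow RBC, 80.3 M for natural sperm, 66.8 M for fast sperm and 69.1 M for slow sperm. Single libraries ranged from 76.2 to 136 M reads in set 1 and from 50.9 to 92.4 M in set 2.

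Over 100000 windows drawn at random, the first principal component held 36.9% of the variance and separated set 1 from set 2, and the second held 7.65% and separated sperm from RBC. The highest correlation between any 2 libraries was 0.930, across windows, so no pair looked like a library deposited more than once. Of the windows called in each of the 8 comparisons between fish, 30.2% to 50.5% lay on the unplaced scaffolds, which held 11.6% to 12% of the tested windows. Where named windows are given below, they were picked so that every library of one group lay above every library of the other. Chance gives this in 10% of orders of 3 against 3, but since the rule asks for it, it adds no support. Most regions at an unadjusted p under 1e-05 also had it (490 of 500 in RBC of set 1), so counts of regions without overlap add none either. P-values are adjusted ones from edgeR's quasi-likelihood test, and levels are normalised CPM (mean ± SD, n = 3).

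In RBC of set 1, hatchery and natural-origin fish differed at scattered single windows, most of them slightly lower in hatchery fish. The window on chromosome 9 from 66574001 to 66575000 was 8.18-fold higher in hatchery RBC (1.00 ± 0.41 against 0.136 ± 0.163 CPM, adjusted p = 0.000441). Nearby windows on chromosome 22 lay lower, with log2 differences of -1.14 ± 0.13 from 43506001 to 43507000 (1.14 ± 0.25 against 2.54 ± 0.28, adjusted p = 0.000169) and -1.07 ± 0.13 from 43496001 to 43497000 (adjusted p = 0.000441). The window on chromosome 20 from 3903001 to 3904000 was 2.49-fold lower (0.471 ± 0.039 against 1.17 ± 0.09), and a stretch of 3 windows on chromosome 12 from 16165001 to 16168000 was 1.62-fold lower at its strongest window (3.08 ± 0.12 against 4.97 ± 0.42). The densest 100 kb held 8 called windows, all lower, from position 79400001 of chromosome 8. Of 1978982 windows tested, 1052 were called, 88 higher and 964 lower in hatchery fish, and 914 of them differed by under 2-fold. At an unadjusted p under 1e-05 there were 500 regions, 490 of them with no overlap between the groups. With each library's trend on window abundance taken out, 93 windows were called, 38 higher and 55 lower. The count was 3123 without natural replicate 1, 116 without natural replicate 2, 135 without natural replicate 3, 213 without hatchery replicate 1, 248 without hatchery replicate 2 and 696 without hatchery replicate 3.

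In sperm of set 1, most differences were gains in hatchery fish of 2-fold or more. Again, the window of chromosome 9 from 66574001 was higher, by 16.5-fold (0.777 ± 0.282 against 0.0458 ± 0.0047 CPM, adjusted p = 9.50e-08). Windows on chromosome 25 from 22630001 to 22631000 (16.3-fold), chromosome 28 from 37762001 to 37763000 (log2 difference 3.59, 0.677 ± 0.240 against 0.0558 ± 0.0116) and chromosome 14 from 72347001 to 72348000 (9.95-fold) were higher as well. An unplaced window from 166447001 had 219, 117 and 64 reads in the hatchery libraries and 2, 0 and 0 in the natural ones (adjusted p = 3.56e-09). Lower in hatchery sperm were the windows on chromosome 11 from 16793001 to 16794000 (6.71-fold, 0.0676 ± 0.0257 against 0.465 ± 0.100, adjusted p = 0.000305), chromosome 6 from 63999001 to 64000000 (9.14-fold) and chromosome 26 from 35231001 to 35232000 (2.97-fold). Of 2022738 windows tested, 410 were called, 349 higher and 61 lower, and 388 differed by 2-fold or more. There were 389 regions at an unadjusted p under 1e-05, 377 without overlap of the groups. The count was 843 without natural replicate 1, 171 without natural replicate 2, 706 without natural replicate 3, 204 without hatchery replicate 1 and 185 without hatchery replicate 3.

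A direct test of whether the hatchery difference of set 1 was unlike in sperm and RBC called 56 windows. At 54 of them the hatchery minus natural difference was higher in sperm than in RBC. The unplaced window from 72434001 had the lowest p, with a difference of differences of 2.95 ± 0.37 (log2 ± SE), made of 1.87 in sperm and -1.07 in RBC. On placed chromosomes, the window of chromosome 29 from 32757001 to 32758000 had 1.67 ± 0.24, that of chromosome 20 from 20502001 to 20503000 had 2.22 ± 0.32 and that of chromosome 11 from 2450001 to 2451000 had 2.09 ± 0.30. Over the 56 windows the median hatchery difference was 1.50 in sperm and -0.46 in RBC. Without replicate 1, 2 or 3 of every group, the count was 23, 33 or 1, and with the abundance trend taken out it was 29. With the title number as a block it was 384, though the labels do not say that the numbers mark fish.

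In RBC of set 2, fast-growth hatchery fish differed from natural-origin fish mainly by losses. The strongest stretch was 4 unplaced windows from 131884001 to 131888000, 3.56-fold lower at the window from 131886001 (1.25 ± 0.38 against 4.47 ± 0.24 CPM, adjusted p = 5.46e-08). Windows on chromosome 5 from 70411001 to 70412000 (2.18-fold), chromosome 10 from 2863001 to 2864000 (2.52-fold, 0.871 ± 0.197 against 2.21 ± 0.33) and chromosome 16 from 4685001 to 4686000 (2.45-fold) were lower too. Higher in fast fish were the windows on chromosome 8 from 79828001 to 79829000 (4.26-fold, 1.65 ± 0.42 against 0.396 ± 0.176, adjusted p = 5.25e-05) and chromosome 26 from 37638001 to 37639000 (4.00-fold, 1.04 ± 0.25 against 0.253 ± 0.069). Of 1879371 windows tested, 129 were called, 14 higher and 115 lower, with 192 regions at an unadjusted p under 1e-05 and 184 of those without overlap. With the abundance trend taken out, 29 windows were called higher and 63 lower. The count rose to 7059 without natural replicate 2 and to 225 without fast replicate 3.

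Slow-growth hatchery RBC differed from natural RBC of set 2 in both directions. A block of 9 windows within 35519001 to 35529000 of chromosome 26 was lower, by 3.09-fold at its strongest window (0.753 ± 0.308 against 2.29 ± 0.41 CPM, adjusted p = 8.94e-05). Lower in fast fish, the window of chromosome 10 from 2863001 was 3.00-fold lower in slow fish as well (adjusted p = 7.86e-05). Windows on chromosome 16 from 659001 to 660000 (9.93-fold, 0.0951 ± 0.0747 against 0.913 ± 0.182, adjusted p = 1.60e-05) and chromosome 4 from 83051001 to 83052000 (3.68-fold) were lower. The highest-ranked gains were on unplaced scaffolds, at the windows from 96359001 (4.32-fold, 1.97 ± 0.08 against 0.470 ± 0.133, adjusted p = 5.06e-07), 221111001 (4.80-fold) and 207096001 (2.82-fold). Of 1786203 windows tested, 152 were called, 58 higher and 94 lower, with 193 regions at an unadjusted p under 1e-05 and 186 of those without overlap. The count was 337 without slow replicate 1 and 234 without natural replicate 3.

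Between fast and slow hatchery RBC, single windows differed by more than 10-fold while most called windows differed slightly. The window of chromosome 12 from 88537001 to 88538000 was 14.8-fold lower in slow fish (0.138 ± 0.072 against 1.98 ± 0.24 CPM, adjusted p = 3.60e-10), and that of chromosome 9 from 65351001 to 65352000 was 11.9-fold higher (1.64 ± 0.28 against 0.136 ± 0.066, adjusted p = 3.28e-09). Slow fish were 4.37-fold lower at the window of chromosome 15 from 1032001 to 1033000, and 8 windows of the chromosome 26 block, from 35520001 to 35529000, were lower by 2.71-fold at the strongest (1.36 ± 0.66 against 3.70 ± 0.18). Higher in slow fish were the windows on chromosome 8 from 78536001 to 78537000 (3.29-fold, 2.46 ± 0.21 against 0.744 ± 0.101) and chromosome 10 from 724001 to 725000 (2.13-fold). Of 1870351 windows tested, 1846 were called, 1685 higher and 161 lower in slow fish, and 1549 differed by under 2-fold. At an unadjusted p under 1e-05 there were 642 regions, 634 without overlap. Scaling by library totals gave 349 higher and 115 lower, and taking out the abundance trend gave 72 higher and 74 lower. The count was 207 without fast replicate 1, 443 without fast replicate 2, 370 without fast replicate 3, 948 without slow replicate 1, 5506 without slow replicate 2 and 748 without slow replicate 3.

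**Figure D1:**
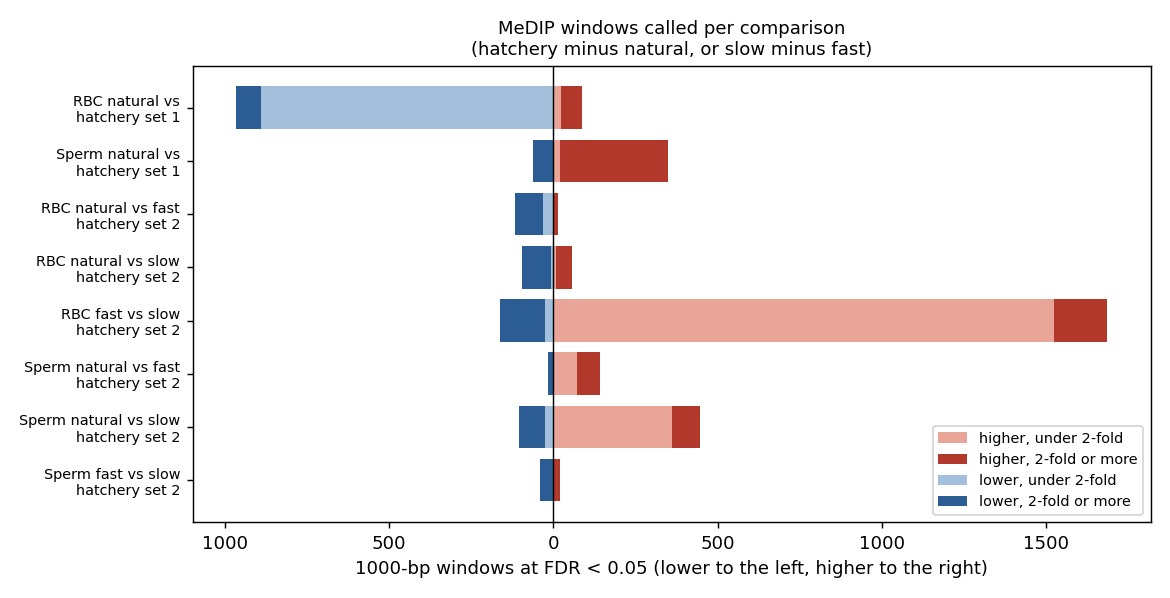
Number of 1000-bp windows called at an adjusted p under 0.05 in each of the 8 comparisons between fish; bars to the right are windows higher in hatchery (or slow) fish and bars to the left are lower, with dark parts for differences of 2-fold or more and pale parts for smaller ones. In RBC the pale parts make up 914 of 1052 windows in set 1 and 1549 of 1846 between fast and slow fish. The dark parts make up 96 of 129 (fast) and 135 of 152 (slow) in RBC against natural fish. In sperm the dark parts make up 388 of 410 in set 1, 87 of 159 for fast against natural and 61 of 62 for slow against fast fish. For slow against natural sperm the pale parts make up 385 of 551.

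In sperm of set 2, fast-growth fish carried the same gains on chromosomes 8 and 26 as in RBC. The window from 79828001 of chromosome 8 was 4.74-fold higher than in natural sperm (2.01 ± 0.46 against 0.421 ± 0.112 CPM, adjusted p = 2.07e-05) and that from 37638001 of chromosome 26 was 6.28-fold higher (1.06 ± 0.22 against 0.165 ± 0.062, adjusted p = 7.63e-05). A stretch of 9 windows on chromosome 4 from 75600001 to 75611000 was higher by 1.86-fold at its strongest window (10.5 ± 0.5 against 5.61 ± 0.37, adjusted p = 0.00411). The call at that window ended when natural replicate 1, 2 or 3 was left out (adjusted p = 0.159, 0.0778 and 0.110) and when the abundance trend was taken out (adjusted p = 0.154, over all alternatives 1.01e-09 to 0.159), and over the fits with a replicate left out its log2 difference stayed positive. The window from 131885001 of the unplaced sequence was 2.11-fold lower in fast sperm and that of chromosome 5 from 70411001 was 2.04-fold lower. Without natural replicate 1 their adjusted p was 0.0706 and 0.105, and without natural replicate 2 that of the chromosome 5 window was 0.0778 (over all alternatives 3.03e-09 to 0.0706 and 2.55e-08 to 0.105). Of 1895820 windows tested, 159 were called, 143 higher and 16 lower, with 231 regions at an unadjusted p under 1e-05, all 231 without overlap. Taking out the abundance trend left 17 higher and 12 lower. At windows over 4-fold lower in sperm than in RBC, fast sperm lay below natural sperm (median log2 difference -0.43, 612 windows), and natural sperm held 18.1% of the RBC level there against 12.8% in fast sperm. The count was 28029 without fast replicate 3, 82 without fast replicate 1, 26 without fast replicate 2, and 17, 21 and 29 without natural replicate 1, 2 and 3.

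Of the leading windows of slow-growth sperm, 6 of 10 higher and 8 of 10 lower ones were also called in slow-growth RBC. The unplaced windows from 207096001 (4.01-fold, 2.32 ± 0.23 against 0.579 ± 0.091 CPM, adjusted p = 1.17e-08), 96358001 (4.31-fold) and 221111001 (6.07-fold) were higher than in natural sperm. On chromosome 4, 9 windows within 75604001 to 75615000 were higher, by 1.73-fold at the strongest (13.4 ± 1.1 against 7.71 ± 0.32, adjusted p = 2.98e-07). The block of chromosome 26 from 35520001 to 35529000 was lower by 2.54-fold at its strongest window (1.40 ± 0.50 against 3.52 ± 0.27, adjusted p = 1.36e-05), and the window of chromosome 4 from 83051001 was 3.26-fold lower. Of 1905680 windows tested, 551 were called, 448 higher and 103 lower, and 385 differed by under 2-fold. At an unadjusted p under 1e-05 there were 413 regions, 405 without overlap. At windows over 4-fold lower in sperm than in RBC, slow sperm lay below natural sperm (median log2 difference -0.44, 652 windows; 13.3% against 18.1% of the RBC level). Library totals gave 258 higher and 106 lower, and taking out the abundance trend gave 110 higher and 107 lower. The count was 253 without natural replicate 1 and 268 without natural replicate 2.

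Sperm of fast and slow hatchery fish showed the 2 windows that led in RBC. The window of chromosome 12 from 88537001 was 12.9-fold lower in slow sperm (0.128 ± 0.042 against 1.71 ± 0.33 CPM, adjusted p = 1.12e-08) and that of chromosome 9 from 65351001 was 10.3-fold higher (1.42 ± 0.51 against 0.124 ± 0.104, adjusted p = 1.15e-05). Slow sperm was 7.32-fold lower at the window of chromosome 15 from 1032001 (adjusted p = 7.20e-06), and unplaced windows from 262360001 and 136462001 were 3.72-fold and 6.07-fold lower. Of 1830760 windows tested, 62 were called, 22 higher and 40 lower, and 61 of the 62 differed by 2-fold or more. There were 101 regions at an unadjusted p under 1e-05, 93 of them without overlap. The count was 1190 without fast replicate 3, 26 without fast replicate 2, 26 without slow replicate 2 and 101 without slow replicate 3.

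The direct test of whether the difference between fast and slow fish was unlike in sperm and RBC called 0 of 1871166 windows with edgeR, with 146799 windows at an unadjusted p under 0.05 and 29 under 1e-05. No other tool was run on this interaction. The fit took the RBC and sperm libraries as unpaired. With the title number as a block, 1345 windows were called. The slow minus fast difference was higher in sperm than in RBC at 36 of them and lower at 1309. The block fit was not run with the abundance trend taken out, so that trend may account for part of this split. Without the block, taking out the trend gave 0 calls and 9 windows at an unadjusted p under 1e-05. The labels do not say that the numbers mark fish, as the closing section gives. It was thus not settled whether the difference was alike in both tissues.

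**Figure D2:**
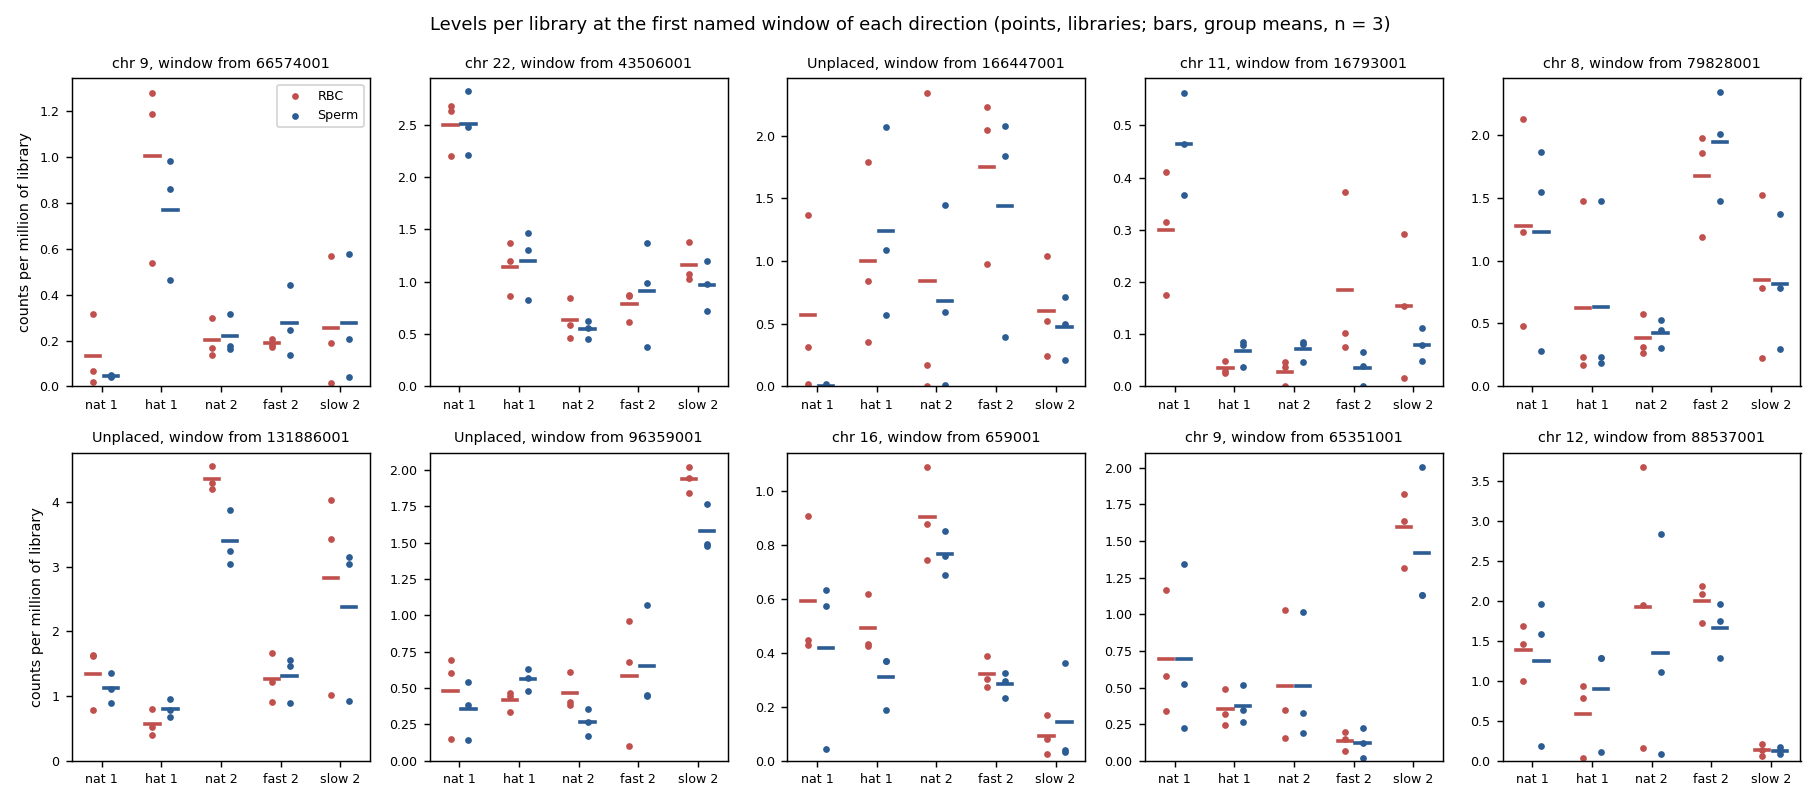
CPM of the library (vertical axes) at the first named window of each direction in 5 comparisons, for natural (nat), hatchery (hat), fast and slow fish of set 1 and set 2; points are libraries, short bars are group means of 3, red is RBC and blue is sperm. At the window of chromosome 12 from 88537001, slow fish of set 2 lay at 0.134 ± 0.069 in RBC and 0.128 ± 0.043 in sperm, and natural fish of set 2 spread from 9 to 318 reads in RBC and from 6 to 235 in sperm.

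Windows called in RBC with a difference of 2-fold or more mostly had the same direction in sperm. This held for 134 of 136 such windows for hatchery against natural fish of set 1 (98.5%, 94.8% to 99.8%), 94 of 96 for fast against natural fish (97.9%, 92.7% to 99.7%), 134 of 135 for slow against natural fish (99.3%, 95.9% to 100.0%) and 276 of 294 for slow against fast fish (93.9%, 90.5% to 96.3%). RBC windows called with a smaller difference had the same direction in 60.6%, 84.8%, 100% and 36.3% of cases in the same order. In the other direction, sperm windows called with 2-fold or more had the same direction in RBC in 57.1%, 76.7%, 98.8% and 100% of cases. With the abundance trend taken out, the lists of called windows changed. RBC windows called with under 2-fold then had the same direction in 46 of 46, 31 of 33, 51 of 51 and 36 of 36 cases. Sperm windows called with 2-fold or more then had it in 57.1%, 100%, 99.2% and 100%. The lower shares of small RBC differences were thus not seen with that correction. Across all tested windows, which are not independent replicates, 47.9% to 52.6% had the same direction. Of the named windows, 8 to 10 of each list of 10 had the same direction in the other tissue.

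**Figure D3:**
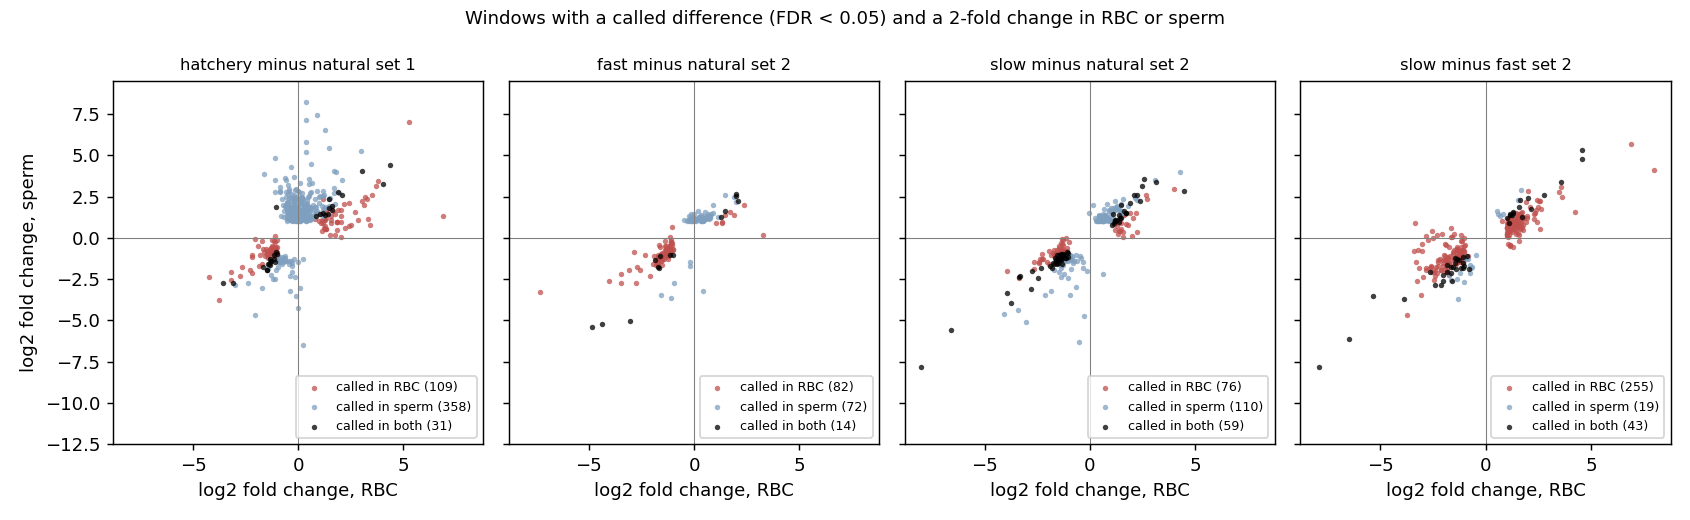
Log2 difference in RBC (horizontal axes) against sperm (vertical axes) in the 4 contrasts. Shown are windows called in either tissue that differed by 2-fold or more in either tissue, called there or not. Red points were called in RBC alone, blue in sperm alone and black in both. Of the windows called in RBC with 2-fold or more in RBC, 134 of 136 had the same sign in sperm for hatchery minus natural fish of set 1. For slow minus fast fish, 276 of 294 did.

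The hatchery differences of set 1 were compared with those of set 2, whose natural and hatchery fish were other libraries. Growth of the hatchery fish was labelled Standard in set 1 and fast or slow in set 2. Of 2023 RBC windows at an unadjusted p under 1e-04 in set 1, 92.6% had the same direction in fast fish of set 2, and of 2009 windows tested in slow fish 33.2% did. With the abundance trend taken out, the shares were 70.8% and 50.5%. In sperm the shares were 70.2% for fast and 66.2% for slow fish, and 59.0% for fast fish with the trend taken out. Of the windows at that p in set 2, 72.8% (fast) and 47.5% (slow) in RBC and 47.7% (fast) and 55.4% (slow) in sperm had the same direction in set 1. Across all windows the correlation of log2 differences between sets was 0.0424 (fast) and -0.0213 (slow) in RBC, and 0.0367 and 0.0343 in sperm. The window of chromosome 9 from 66574001 ranked first among those higher in hatchery RBC of set 1. In set 2 it had log2 differences of -0.20 ± 0.38 (fast) and 0.27 ± 0.53 (slow) in RBC, neither of them called.

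Fast and slow fish were both set against the same natural libraries of set 2. At an unadjusted p under 1e-04 the lists shared 86 windows of the same direction in RBC, 73 of them lower than natural, and 298 in sperm, 280 of them higher. Independent lists of these sizes would share 0.165 and 0.693 windows. Simulated fast and slow groups without any effect, set against the same simulated natural libraries, shared 3 in each tissue. All 9 libraries of a tissue were drawn from the window means and the dispersion trend. The simulation thus lacks anything particular to the real natural libraries. The simulated lists were shorter, with 148 and 154 windows for RBC and 181 and 159 for sperm against 766 and 770 and 1336 and 1325 observed, so these overlaps are not on one footing. The correlation of the log2 differences was 0.521 observed and 0.522 simulated for RBC, and 0.472 and 0.466 for sperm. The covariance of the log2 differences was 0.0842 against 0.0741 in the simulation for RBC and 0.0766 against 0.0672 for sperm. With 3 natural libraries the controls could not be split, so part of the excess may come from the shared controls. The windows of chromosome 10 from 2863001 and chromosome 16 from 4685001 were called lower in RBC of both fast and slow fish.

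Sperm and RBC were compared with 6 or 9 libraries per side, so their counts are not on one footing with those between groups of 3. Sperm was higher at the window of chromosome 2 from 49192001 to 49193000, by 13.2-fold in set 1 (2.96 ± 0.32 against 0.224 ± 0.049 CPM, n = 6, adjusted p = 2.04e-25) and by 19.6-fold in set 2 (2.35 ± 0.24 against 0.115 ± 0.056, n = 9, adjusted p = 2.13e-26). At the window of chromosome 8 from 49257001, sperm was higher by 9.88-fold and 10.0-fold. Lower in sperm were the windows of chromosome 25 from 34137001 (37.7-fold and 11.8-fold), chromosome 9 from 10582001 (31.3-fold and 27.4-fold), chromosome 29 from 15750001 (40.2-fold and 28.2-fold), chromosome 2 from 42712001 (31.0-fold and 36.4-fold) and chromosome 18 from 49318001 (29.2-fold and 14.3-fold). In set 1, 160617 of 2007704 windows were called, 71571 higher and 89046 lower in sperm, and in set 2, 60194 of 1871166, 41257 higher and 18937 lower. Library totals gave 86259 higher and 71009 lower in set 1. These fits took the RBC and sperm libraries as unpaired. With the title number as a block, 197879 windows were called in set 1 and 64220 in set 2. Without replicate 1, 2 or 3 of every group the counts were 99257, 75975 and 59276 in set 1 and 32414, 29451 and 35901 in set 2. At an unadjusted p under 1e-05 there were 25560 regions in set 1, 22960 without overlap, and 17269 in set 2, 10941 without overlap.

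In both sets together, 31208 windows were called, 23630 higher in sperm in both, 7432 lower in both and 146 in opposite directions, and the correlation of the tissue difference between sets was 0.467 across windows. Losses in sperm formed longer runs than gains. Counting called windows with gaps of at most 1 window between them, runs of at least 10 windows numbered 16 for losses and 0 for gains, and runs of at least 5 numbered 54 and 22. The longest losses lay on chromosome 14 from 10130001 to 10155000 (22 called windows, 6.59-fold lower on average), on chromosome 25 from 22524001 to 22546000 (21 windows, 8.89-fold) and from 22574001 to 22596000 (20 windows, 5.83-fold), and on chromosome 18 from 49317001 to 49340000 (18 windows, 8.72-fold). The longest gain lay on chromosome 7 from 491001 to 501000 (7 windows, 3.67-fold). On the mitochondrial genome, 9 of 17 windows in set 1 and 8 of 17 in set 2 were lower in sperm.

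**Figure D4:**
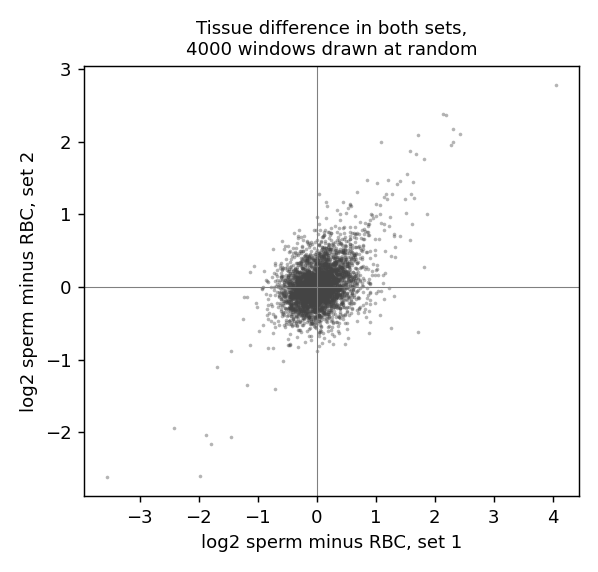
Log2 difference of sperm minus RBC in set 1 (horizontal axis) against set 2 (vertical axis) for windows drawn at random, one point per window. The correlation over all 1862712 windows tested in both sets was 0.467.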

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

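The abundance correction in this part was chosen after seeing the data; the other tests were written down before their result was seen. In set 1, the difference between hatchery and natural fish was not the same in sperm as in RBC at 56 windows, by a direct test of that difference. Of these, 54 had the higher hatchery minus natural difference in sperm, 51 were also called in sperm alone, and 27 lay on unplaced scaffolds. Splits of the libraries were fitted on a sample of 90000 windows, where the real grouping gave 0 calls, so that 100 of 100 splits had to give as many (highest other 36) and this count says nothing about chance. At an unadjusted p under 1e-05 the real grouping gave 3 windows, and 51 of the 100 splits gave at least as many, so chance was not excluded. DNA of blood cells in the hatchery sperm would raise windows that sperm lacks. At 1370 windows over 4-fold lower in sperm in set 2 the median hatchery difference in sperm of set 1 was -0.10 (interquartile range -0.54 to 0.35), with no rise. Over 1888 such windows, natural replicate 2 held 19.0% of the RBC level. The other natural libraries held 12.5% and 13.4%, and hatchery sperm 13.5% to 14.2%. The sign of the median may thus rest on natural replicate 2, and it argues against that source only weakly. With each library's abundance trend taken out, 51.8% of the 56 windows were called in the same direction, too near to equal parts to decide whether that trend accounts for them. A difference between the tissues in how hatchery and natural fish are methylated stays open and was not tested further. The test does not tell whether it lies in natural or in hatchery fish. At the window of lowest p, mean CPM was 0.213 in natural and 0.769 in hatchery sperm, against 1.08 and 0.504 in RBC. The count rests on replicate 3, since 1 window was called without it, 23 without replicate 1 and 33 without replicate 2.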

How the results depend on the processing

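The fits without each library's abundance trend, with counts corrected for a ceiling, with bias-adjusted deviances and with a trend over every window were chosen after seeing the data; all other alternatives were fixed before. Numbers of called windows are given throughout, and where they moved by over 1.5 times the cause was not tested, except that leaving out libraries or raising the count minimum leaves fewer samples or windows. RLE factors and a trend over every window left each count tested with them within 1.5 times of its main value.

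With DESeq2 the counts were 4673 for RBC of set 1 (main value 1052), 276 for RBC of fast against natural fish (129), 96 for RBC of slow against natural fish (152), 11883 for RBC of slow against fast fish (1846), 7245 for sperm of fast against natural fish (159) and 892 for sperm of slow against natural fish (551). With edgeR's exact test they were 625 (RBC, set 1), 1124 (sperm, set 1, main value 410), 661 and 660 (RBC, fast and slow against natural), 1403 and 1030 (sperm, fast and slow against natural) and 265 (sperm, slow against fast, main value 62). Bias-adjusted deviances gave 1937 (RBC, set 1), 673 (sperm, set 1), 296 and 347 (RBC, fast and slow against natural), 3265 (RBC, slow against fast), and 369 and 869 (sperm, fast and slow against natural). With all 9 libraries of a tissue in one fit, the counts were 51 (RBC, fast against natural), 200 (RBC, slow against fast), 1301 (sperm, fast against natural) and 83 (sperm, slow against natural).

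Library totals gave 509 (RBC, set 1), 464 (RBC, slow against fast), 98 (sperm, fast against natural) and 364 (sperm, slow against natural). Taking out the abundance trend gave 93 (RBC, set 1), 146 (RBC, slow against fast), 29 (sperm, fast against natural), 217 (sperm, slow against natural) and 29 for the interaction of origin and tissue (main value 56). It moved the share of RBC windows of set 1 with the same direction in fast fish from 92.6% to 70.8%, turned that in slow fish from 33.2% to 50.5%, and moved that of sperm in fast fish from 70.2% to 59.0%. Counts corrected for a ceiling gave 426 (RBC, set 1) and 844 (RBC, slow against fast). Without a filter the counts were 1930 (RBC, set 1), 354, 637 and 3021 (RBC, fast against natural, slow against natural and slow against fast), and 1018, 993 and 160 (sperm, in that order), and a summed count of at least 90 gave 759 (RBC, slow against fast) and 49 (sperm, fast against natural). At p under 1e-05 the fast and slow lists shared 17 windows in RBC and 72 in sperm.

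Leaving out 1 library at a time gave 116 to 3123 (RBC, set 1), 171 to 843 (sperm, set 1), 87 to 7059, 138 to 337 and 207 to 5506 (RBC, fast against natural, slow against natural and slow against fast), and 17 to 28029, 253 to 645 and 26 to 1190 (sperm, in that order). Leaving out 1 replicate number gave 59276 to 99257 and 29451 to 35901 for sperm against RBC in set 1 and set 2, 1 to 33 for the origin interaction and 0 for the growth interaction. Between fish, 61 of 80 named windows kept their call and 0 turned direction over the 1328 fits that gave an adjusted p; the call was lost in 42 of these, 33 of them with a library left out, and DESeq2 gave no adjusted p in 32 more cases. All 20 named windows of sperm against RBC kept their call in their 180 fits.

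The title numbers recur in the groups, but the labels do not say that they mark a shared fish. With the number as a block the counts were 883 (RBC, set 1), 1184 (sperm, set 1), 197879 and 64220 (sperm against RBC, set 1 and set 2), 384 (origin interaction) and 1345 (growth interaction, main value 0). Over all windows, the RBC and sperm libraries of one number had correlations of their deviations over 0.1 in 3 of 6 pairs of set 1 and 5 of 9 pairs of set 2. As a hint from the data only, over the 2000 most variable windows every sperm library correlated best with the RBC library of its own number, in 6 of 6 and 9 of 9 pairs (0.362 to 0.800, highest other 0.167). Across hatchery and natural fish of set 1, libraries sharing a number had correlations of -0.057 to 0.078, so that block pairs no fish there.

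The promoter comparisons and their alternatives were not run, since the gene table at hand belongs to another assembly, and the alternative on CpG coupling was not run. At the real depths and with 3 libraries per group, simulated 2-fold changes were recovered in 14% to 39% of windows between fish and 4-fold ones in 70% to 81%; depth was not varied on its own, so its part in this was not tested.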

Other observations

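The test of deviations between libraries below was written down after its result was seen, and the abundance correction and the count correction were chosen after seeing the data, and the share of windows with the same direction under that correction was widened to every window after a first share had been seen; the other tests were written down beforehand. Gains in sperm over RBC found in both sets were spread over all chromosomes, at 10.9 (chromosome 23) to 16.6 (chromosomes 13 and 21) windows per 1000 tested, against 7.94 on the unplaced scaffolds. Among the chromosomes, losses were most frequent on chromosome 13 (7.32 per 1000) and the unplaced scaffolds had 2.19. The 1888 windows called over 4-fold lower in sperm in set 2 still held 13.9% ± 0.35 of the RBC level in hatchery sperm of set 1, 15.0% ± 3.5 in natural sperm of set 1, 12.8% ± 1.1 in fast, 13.3% ± 2.4 in slow and 18.1% ± 2.3 in natural sperm of set 2 (SD, n = 3). Among these windows, the median log2 difference from natural sperm of set 2 was -0.43 in fast sperm (612 windows tested) and -0.44 in slow sperm (652 tested), and that of the 17 mitochondrial windows was -0.44 and -0.69. How much of the calls between hatchery and natural sperm of set 2 goes with this higher RBC-like level in natural sperm was not tested. On the mitochondrial genome, 3 of 17 windows were called lower in slow than in natural sperm of set 2 and 0 of 17 in each other comparison between fish, by edgeR.

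Some windows had many reads in some libraries of a group and few in others. The window of chromosome 12 from 88537001 had 9 to 318 reads in natural RBC and 6 to 235 in natural sperm of set 2, against 5 to 12 in both tissues of slow fish and 157 to 202 in fast RBC. The window of chromosome 13 from 7485001 had 2 reads in each fast sperm library, 5 to 164 in natural and 4 to 155 in slow sperm, and its call between fast and slow sperm ended without fast replicate 2 (adjusted p = 0.0693 by edgeR), with DESeq2 (adjusted p = 0.318) and in the fit of 9 libraries (adjusted p = 0.0520), over alternatives from 1.07e-10 to 0.318.

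RBC windows with a called difference under 2-fold lay mostly on one side: 889 of 914 lower in hatchery fish of set 1, and 1525 of 1549 higher in slow than in fast fish. The groups also differed in depth (125 against 90.7 M reads in set 1, 65.0 against 90.4 M for slow against fast) and in the ratio of the 99th percentile to the median window count (10.6 ± 0.55 against 11.5 ± 0.25, and 14.3 ± 0.40 against 11.5 ± 0.06). With each library's trend of count on abundance taken out, 2.59% and 0.459% of these windows kept their call, and their median log2 difference went from -0.41 ± 0.14 to -0.19 ± 0.21 and from 0.53 ± 0.13 to 0.26 ± 0.21 (SD over windows), so the calls ended because the differences shrank; a trend between libraries may account for much of them, but the same correction would also remove a real methylation difference spread over abundant windows, which stays open. With counts corrected for a ceiling, 34.9% and 40.3% kept their call, as a ceiling would predict, yet the medians stayed at -0.40 ± 0.18 and 0.53 ± 0.14 and the calls ended through slightly larger p-values (medians from 9.14e-06 to 2.02e-05 and from 1.66e-05 to 3.16e-05), and since the ceiling was assumed it cannot be told whether saturation plays a part.

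RBC windows with a called difference of 2-fold or more had the same direction in sperm in 93.9% to 99.3% of cases in the 4 contrasts. With each library's abundance trend taken out, the lowest share over the 4 contrasts, over every one of these windows, was 94.2%. The windows were picked for large differences in RBC. In sperm the correction moved their median difference little (1.08 to 1.09 in set 1, 1.03 to 1.11 for fast against natural fish). Directions could thus hardly turn, so the share cannot decide whether that trend was a source of the direction shared by these windows. Fewer of them were still called in RBC (50 of 136, 63 of 96, 126 of 135 and 116 of 294 in the order of the report), although the median size of their log2 differences stayed, from 1.47 ± 0.96 to 1.48 ± 0.96 in set 1 and from 1.45 ± 0.97 to 1.48 ± 0.98 for slow against fast fish (SD over windows), and why those calls ended was not tested. Over these windows, RBC and sperm libraries with the same title number deviated together from their group means (median r = 0.740 across windows, 0.299 to 0.827, over 15 pairs). A candidate explanation, as a hypothesis found on the same data, is that such windows differ between individual fish in both tissues, for example through sequence or copy-number differences or methylation set early in development. The labels do not say that each library came from its own fish or that a number marks a fish, so this stays a hypothesis about the fish or pools behind the libraries. Origin or growth acting on both tissues stays open too, and no test here separates it from the choice of the fish or pools sampled.

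Other splits of the libraries were fitted on samples of the tested windows. The 10 splits of 3 against 3 libraries are too few for a share under 0.05. On 400000 windows the real split and the highest other gave 204 and 44 calls (RBC, set 1), 88 and 31 (sperm, set 1), 32 and 19 (RBC, fast against natural), 35 and 19 (RBC, slow against natural), 524 and 20 (RBC, slow against fast), 35 and 160 (sperm, fast against natural), 126 and 19 (sperm, slow against natural) and 9 and 21 (sperm, slow against fast). As many calls as the real split came from 2 of the 10 splits, the real one included, in sperm of fast against natural and of slow against fast fish, and from 1 in the other 6 comparisons. In sperm of fast against natural fish the split with 160 calls exceeded the real one, and what sets those libraries apart was not tested. Between sperm and RBC chance was excluded: on 20000 windows 1 of 100 splits, the real one, gave as many, with 1677 against 161 calls for the highest other in set 1 and 654 against 2 in set 2. For the growth interaction the real split gave 0 calls on 90000 windows, so that 100 of 100 splits had to give as many (highest other 22) and this count says nothing about chance. At an unadjusted p under 1e-05 the real split gave 1 window, and 55 of the 100 splits gave at least as many, so chance was not excluded.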
